A study of Mus musculus with 3 samples.

How the data were processed

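RNA was measured in medial edge epithelium of palates of CF-1 mouse embryos at embryonic day 13.5, with 1 array at each of 0, 12 and 24 h. Per the labels' protocols, the epithelium was freed with the enzyme Dispase II, RNA was purified on columns, amplified with the RiboAmp kit, labelled with biotin by the ENZO kit and hybridized to Affymetrix arrays of 1 colour. The labels name Microarray Suite 5.0 and GeneSpring 6.0 for the analysis by the submitters, without saying which of them wrote the values. How many embryos went into a sample is not given in the sources used here.

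The values used are the deposited intensities, 1 linear signal per probe set, never negative and without detection calls. Their 2% trimmed means differ between arrays, so no common scaling was evident, and whether any scaling had been applied is not stated in the labels. Of 12488 probe sets, 66 are controls, which served as quality measures alone. Of the other 12422, 10833 name 1 gene, 396 several and 1193 none. Only those naming 1 gene entered gene counts. Symbols were looked up by gene identifier in a RefSeq gene table (assembly GRCm38.p6), which matched 10817 of the 10833. That table was also used for the order of genes along chromosomes, without coordinates.

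Each array was scaled to a common 2% trimmed mean over non-control probe sets, the geometric mean of the 3 arrays, by factors of 0.676 at 0 h, 1.09 at 12 h and 1.36 at 24 h. Scaled signals were then floored at the pooled 40th percentile, a signal of 13.5, and taken to log2. A gene with both arrays at the floor has no ratio, and a gene with 1 array at the floor has a bound, written as at least N-fold against the floor. A gene is represented by its probe set of highest mean signal, and 2073 of 8251 genes have several probe sets. In all, 4682 genes were above the floor on all 3 arrays and 1682 on none. Scaling sets what counts as higher: the median log2 ratio over all genes was -0.21, 0.17 and -0.08 for 12 h over 0 h, 24 h over 12 h and 24 h over 0 h, while with values as deposited it was -0.83, -0.12 and -0.98. After median centring it was 0.06, -0.01 and 0.04, and after quantile normalization 0.07, 0.01 and 0.03.

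With 1 array per time point no test was possible, and the number of arrays limits the precision. Genes were counted by a rule of size, at least 2-fold. Each of 26 gene lists was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size, matched on mean log2 signal in 20 bins. A percentile at or below 2.5 or at or above 97.5 is called standing apart and describes these arrays. Comparisons, lists, rules and all alternatives but 1 were fixed before the data were examined. Genes named in the text were, for each comparison, the 8 largest measured ratios each way, the 4 brightest genes each way with a bound of at least 2-fold, up to 4 members of each described list with the largest ratios, and 20 genes chosen beforehand from the biology of palate fusion. Of these 20, 1 is not reported here. Names were left out from the end of a ranking for length, and a name kept by 1 ranking can come after omitted ones in another.

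Error was gauged from genes with several probe sets above the floor on both arrays. The SD of the log2 ratio of 1 probe set about its gene's mean was 1.24 for 12 h over 0 h (672 genes), 0.82 for 24 h over 12 h (687 genes) and 1.07 for 24 h over 0 h (748 genes). From these an SD per array of 1.00 at 0 h, 0.73 at 12 h and 0.37 at 24 h followed, and 100 sets of unchanged genes were simulated with them. This error also contains real differences between transcripts probed by different sets, and it is assumed to be normal and independent between genes and between arrays. Deviations shared by the 12 h and 24 h arrays, whose control 3' to 5' ratios were both raised, would be assigned to the 0 h array. The SDs per array therefore do not rank the arrays by precision. Named genes with a ratio of at least 2-fold and another measured probe set numbered 9, 8 and 20 in the 3 comparisons, and in 6, 5 and 14 of them all other sets had the same direction. Ratios close to 0 also counted as a direction, so the same direction does not mean a difference of like size.

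The procedure was tested on simulated data with these errors for 12 h over 0 h, on 8251 genes. Of 50 genes planted at each log2 size, the 2-fold rule recovered 46.0% at 1, 78.0% at 2, 84.0% at 3 and 90.0% at 4, and it also called 37.0% of unchanged genes. A list of 35 genes shifted by a log2 ratio of 1 reached percentile 100, and an unshifted list of 29 genes percentile 96.2.

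Alternatives were values as deposited, median centring, quantile normalization, floors at the 20th and 60th percentile or no floor, the mean over a gene's probe sets, removal of probe sets whose suffix marks possible cross-hybridization, a 3-fold rule and the mean in place of the median of a list. Scaling and flooring from only the 2 arrays of a comparison was added after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.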

Results

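Gene expression was measured in the medial edge epithelium of the mouse secondary palate, the cell layer that covers the tips of the palatal shelves and forms the midline seam when opposing shelves meet. The tissue came from mid-gestation embryos of the CF-1 stock. The 3 arrays held unfused epithelium without culture (0 h), fused epithelium 12 h after the shelves had been brought into contact in culture, and fused epithelium at 24 h, when it was described as transforming from epithelium to mesenchyme. Each time point had 1 array. No ratio below has a replicate check, an error or a p-value, and fusion cannot be separated from time in culture, because the unfused tissue was not cultured.

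The arrays gave a signal for 12422 probe sets other than controls. The trimmed mean of the deposited signals was 93.7 at 0 h, 58.1 at 12 h and 46.8 at 24 h, and the arrays were scaled to a common trimmed mean before any comparison. After scaling, 5878 of 8251 genes lay above the floor at 0 h, 5405 at 12 h and 5742 at 24 h. Across probe sets above the floor on both arrays, log2 signals of 12 h and 24 h correlated at r = 0.825, those of 0 h and 24 h at r = 0.752, and those of 0 h and 12 h at r = 0.667. These correlations are across probe sets, which are not independent replicates.

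The 3' to 5' signal ratios of control transcripts differed between the arrays. Control probe sets for the 3' end of Gapdh, a glycolytic enzyme, gave 0.828 times the signal of those for its 5' end at 0 h, 14.9 times at 12 h and 12.6 times at 24 h. For Actb, cytoplasmic beta-actin, the 3' to 5' ratio was 1.02 at 0 h, 11.9 at 12 h and 2.97 at 24 h. For bacterial control transcripts the ratios at 0, 12 and 24 h were 0.427, 1.10 and 0.789 for BioB, 0.714, 0.682 and 0.794 for BioC, 6.13, 4.26 and 5.23 for BioDn, and 1.51, 1.02 and 0.806 for CreX. Whether all samples had the same number of amplification rounds is not given in the sources used here.

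**Figure D1:**
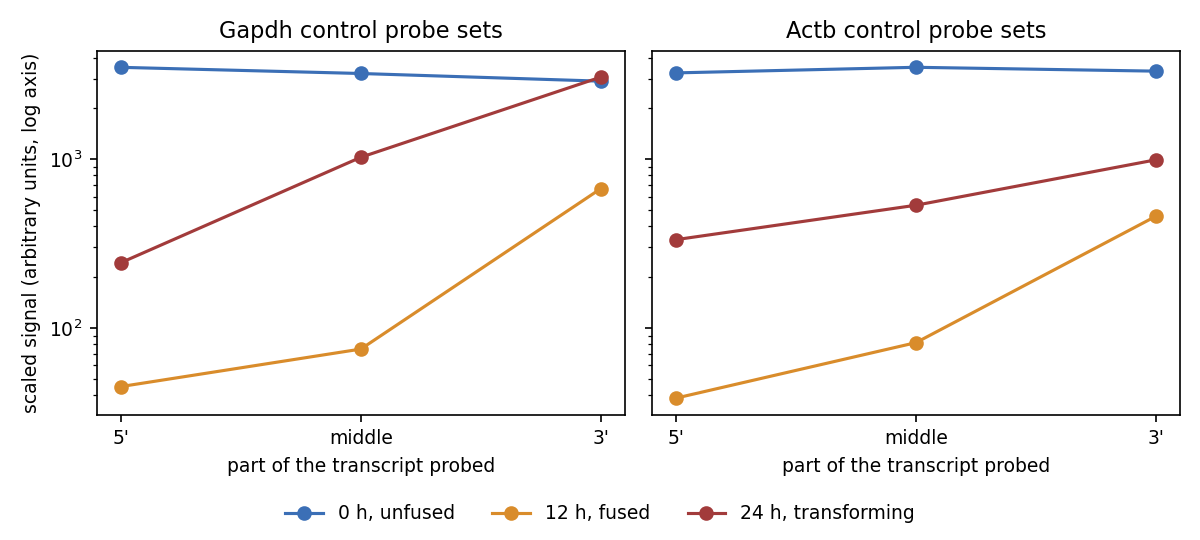
Scaled signals (arbitrary units, log axis) of control probe sets for the 5' end, the middle and the 3' end of Gapdh and Actb, with 1 line per array. The 0 h lines are nearly level, with 3' to 5' ratios of 0.828 and 1.02, and the 12 h and 24 h lines are highest at the 3' end.

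The comparison of 12 h with 0 h asked what differed once the shelves had adhered. Interferon response genes were higher at 12 h, with 15 of 24 members at least 2-fold higher and 1 at least 2-fold lower. Gbp3, an interferon-inducible GTPase, was at least 52.3-fold higher, reaching a scaled signal of 707, and Ifih1, a sensor of double-stranded RNA, at least 12.3-fold higher. Isg15, a ubiquitin-like modifier, was 8.61-fold higher, and Usp18, which removes it from proteins, at least 7.93-fold higher. DNA replication genes were lower, with 21 of 39 members at least 2-fold lower and 4 at least 2-fold higher. Mcm7 and Mcm5, subunits of the replicative helicase, were at least 21.5-fold lower and 9.80-fold lower, and the DNA polymerase delta subunits Pold1 and Pold2 7.41-fold lower and at least 15.8-fold lower. Other probe sets gave log2 ratios of -0.60 for Mcm5 and -0.03 for Pold1.

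Matrix proteases and their inhibitors had 11 of 25 members at least 2-fold higher at 12 h and 6 at least 2-fold lower. The lysosomal proteases Ctss and Ctsl were 12.1-fold and 6.51-fold higher, the collagenase Mmp13 at least 6.67-fold higher, and the lysosomal protease Ctsd 5.01-fold lower. Of 23 genes of periderm and keratinocyte differentiation, 8 were at least 2-fold higher and 1 at least 2-fold lower. Anxa1, an annexin, was 9.58-fold higher, and Krt10, a keratin of differentiating layers, 9.27-fold higher. The desmosomal plakophilin Pkp1 was 8.11-fold higher and the cornified envelope gene Scel at least 3.35-fold higher. The other probe set of Pkp1 gave a log2 ratio of 0.18. Ribosomal protein genes had 1 of 24 members at least 2-fold higher and 8 at least 2-fold lower. Rpsa was 4.94-fold lower, Rpl8 4.28-fold lower and Rps7 4.25-fold lower; Rpl10a was 4.76-fold lower by its brightest probe set and higher, at a log2 ratio of 0.60, by its other one. Genes of oxidative phosphorylation had 19 of 48 members at least 2-fold lower and 7 at least 2-fold higher, among them the ATP synthase genes Atp5l (19.1-fold lower) and Atp5e (15.8-fold lower) and the complex III gene Uqcrc2 (13.7-fold higher).

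The lists closest to the process itself went both ways at 12 h. Epithelial junction and polarity genes had 7 of 30 members at least 2-fold higher and 6 at least 2-fold lower, with the desmosomal cadherin Dsc2 18.9-fold higher and the tight junction claudin Cldn4 at least 15.2-fold lower. Palate mesenchyme markers had 14 of 36 at least 2-fold higher and 12 at least 2-fold lower. This list also stood for cells that an enzyme-separated epithelium could carry along, and such carry-over was not tested. Mfap2, a microfibril component, was 37.8-fold lower and Twist2, a basic helix-loop-helix factor, 12.1-fold lower. The homeobox gene Prrx2 had a log2 ratio of -4.32. Signals of Mfap2, Twist2 and Prrx2 at 0 h, before culture, were 775, 223 and 299. Of 35 genes of epithelial-mesenchymal transformation, 10 were at least 2-fold higher and 6 at least 2-fold lower, with Tgfb2 5.92-fold higher. Tgfb3, the growth factor needed for palatal seam removal, was 2.11-fold higher. Its signal transducers Smad4 and Smad2 were 9.92-fold and 1.87-fold higher, and Smad1, which acts for bone morphogenetic proteins, 12.3-fold higher, while Id1, a target of these proteins, was 12.3-fold lower. Twist1 was 3.01-fold higher and Snai1 at least 3.77-fold lower, and Snai2 had a log2 ratio of 0.58. Ctnnb1, which encodes beta-catenin, was 2.42-fold higher, and Trp63, the regulator of stratified epithelia, 3.03-fold higher. Smaller ratios belonged to Cdh1 (log2 -0.10), Cdh2 (log2 -0.53), Fn1 (log2 -0.11) and Lef1 (log2 -0.38).

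Among all genes measured on both arrays, those with the highest ratios at 12 h were Bach1, a heme-responsive repressor (21.0-fold higher, with a log2 ratio of -0.20 from its other probe set), the copper transporter Slc31a1 (19.0-fold higher), Dsc2 and Rin2 (17.2-fold higher). For Slc31a1 the other probe set gave a log2 ratio of 0.27. The lowest ratios besides that of Mfap2 belonged to Igfbp2, an insulin-like growth factor binding protein (35.7-fold lower), the embryonic globin Hba-x (25.7-fold lower) and Rnf167 (21.9-fold lower). Brightest among genes at the floor at 0 h were Gbp3 and Ibsp, a bone sialoprotein (at least 50.3-fold higher, with a log2 ratio of -0.98 from its other probe set). Those at the floor at 12 h were led by Gnb2, Sec61b and Cdc37, at least 40.1-fold, 35.2-fold and 31.9-fold lower. The adult-type globin Hba-a1 was 10.5-fold lower.

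In all, 1128 of 6379 genes were at least 2-fold higher at 12 h and 1739 at least 2-fold lower, so 39.3% of these differences were upward. That share was 16.8% with the values as deposited, 52.9% with arrays centred on the median and 51.1% after quantile normalization. Simulated unchanged genes, given the disagreement between probe sets of 1 gene as their error, produced up to 1161 higher and 1286 lower genes. Under the main scaling the count of higher genes did not exceed that error. After median centring 1490 genes were higher and 1324 lower, and after quantile normalization 1406 and 1343. Whether the count of higher genes exceeds the simulated counts therefore depends on the scaling. Where a second probe set of a gene was measured, it gave the same direction for 62.8% of 360 genes that were 2-fold different by the brightest set, repeated the 2-fold difference for 28.3% and was 2-fold different the opposite way for 56 genes. Among 26 lists, interferon response (median log2 ratio 1.59, percentile 100), matrix proteases (0.44, percentile 98.6) and periderm (0.42, percentile 98.3) stood above matched random lists, the last under 6 of 10 alternatives. With the values as deposited the periderm median was -0.27, at percentile 98.3, and that over all genes -0.83. DNA replication (-1.15, percentile 0.10), ribosomal proteins (-0.52, percentile 0.040) and oxidative phosphorylation (-0.52, percentile 0.33) stood below them. Epithelial junctions (-0.16, percentile 62.4), palate mesenchyme (0.21, percentile 55.0) and transformation genes (0.07, percentile 78.0) did not stand apart. The control 3' to 5' ratios also differed between these arrays. With 1 array per time point, that difference cannot be separated from those of the lists. Ratios of genes adjacent on a chromosome correlated at r = 0.208 across gene pairs.

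The comparison of 24 h with 12 h covered the passage from a fused to a transforming seam, with both tissues cultured. Genes of glycolysis and hypoxia were higher at 24 h, with 11 of 31 members at least 2-fold higher and 2 at least 2-fold lower. The glycolytic enzymes Pkm and Tpi1 were 6.86-fold and 4.35-fold higher, although the other probe set of Pkm gave a log2 ratio of -0.18. Both were lower at 12 h than at 0 h, and their log2 ratios for 24 h over 0 h were -0.87 and -0.01. P4ha2, a collagen prolyl hydroxylase subunit, was 5.80-fold higher, and Ddit4, a hypoxia-induced inhibitor of mTOR signalling, 4.75-fold higher. Wnt signalling genes were also higher, with 12 of 35 members at least 2-fold higher and 3 at least 2-fold lower. The receptor Fzd2 was at least 10.6-fold higher, the kinase Csnk1e at least 8.93-fold higher, the transducer Dvl2 at least 3.41-fold higher and the receptor Fzd9 3.31-fold higher. Fzd2, Csnk1e and Dvl2 were at the floor at 12 h and had signals of 271, 151 and 117 at 0 h.

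Interferon response genes had 11 of 25 members at least 2-fold higher at 24 h than at 12 h and 0 at least 2-fold lower. The class I histocompatibility genes H2-D1 and H2-K1 were 4.93-fold and 4.30-fold higher, Ifi27 at least 3.66-fold higher and Ifit3 3.28-fold higher, with a log2 ratio of -0.28 from another probe set of H2-K1. In the list of apoptosis genes and p53 targets, Cdkn1a, an inhibitor of cyclin-dependent kinases, was 6.42-fold higher and Gadd45b, a stress-induced gene, 4.92-fold higher. That list had 6 of 32 members at least 2-fold higher and 4 at least 2-fold lower, with a median of 0.13 at percentile 31.0.

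Epithelial junction and polarity genes had 11 of 28 members at least 2-fold higher at 24 h and 4 at least 2-fold lower. Cldn4 was at least 6.10-fold higher, the epithelial transcription factor Elf3 at least 5.85-fold higher, the simple epithelial keratin Krt8 4.38-fold higher and Cldn7 at least 4.04-fold higher. Cldn4 had signals of 206 at 0 h and 82.6 at 24 h and was at the floor at 12 h. Palate mesenchyme markers had 11 of 33 at least 2-fold higher and 3 at least 2-fold lower. Prrx2 was 22.8-fold, Mfap2 8.31-fold, Twist2 5.62-fold and the Notch ligand-like Dlk1 5.26-fold higher, after lower signals at 12 h than at 0 h. Of 34 transformation genes, 7 were at least 2-fold higher and 6 at least 2-fold lower, with the integrin Itgav 4.90-fold lower (log2 ratios of -0.96 and 0.17 from its other probe sets) and the gelatinase Mmp9 3.77-fold higher. Ctnnb1 was 2.58-fold lower, Trp63 3.41-fold lower, Cdh2 2.61-fold lower and Cdh1 1.58-fold lower. Smad4 was 2.04-fold lower. Log2 ratios were 0.34 for Tgfb3, 0.26 for Smad2, -0.12 for Twist1, 0.06 for Snai2, 0.45 for Fn1 and 0.43 for Lef1.

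The highest measured ratios besides Prrx2 were those of Rnf167 (13.0-fold higher), the elongation factor Eef2 (11.4-fold higher) and Ssr2 (11.1-fold higher). In the other direction stood the phosphatase subunit Ppp1cb (26.7-fold lower), the aryl hydrocarbon receptor Ahr (14.5-fold lower), the endoplasmic reticulum chaperone Dnajb9 (9.97-fold lower) and Mgst1 (9.02-fold lower). Igfbp4 and Gnb2 were the brightest of genes at the floor at 12 h (at least 16.8-fold and 16.2-fold higher) and Fmr1 and Topbp1 of genes at the floor at 24 h (at least 10.4-fold and 8.40-fold lower). Other probe sets of Igfbp4 gave log2 ratios of 0.72 and 0.50. Rnf167, Eef2, Igfbp4 and Gnb2 had lower signals at 24 h than at 0 h.

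In all, 1157 of 6141 genes were at least 2-fold higher at 24 h than at 12 h and 737 at least 2-fold lower, against at most 581 and 705 in simulated unchanged genes. After median centring the observed counts were 911 and 967, and after quantile normalization 906 and 876. Second probe sets gave the same direction for 69.6% of 240 genes, repeated the 2-fold difference for 26.7% and were 2-fold different the opposite way for 12 genes. The upward share was 61.1%, compared with 39.4% for values as deposited, 48.5% after median centring and 50.8% after quantile normalization. Glycolysis and hypoxia (median log2 ratio 0.69, percentile 99.7) and Wnt signalling (0.59, percentile 97.9) stood above random lists, and none of the 26 lists stood below, although oxidative phosphorylation (-0.34, percentile 3.22) did under 5 of 10 alternatives. Glycolysis and hypoxia stood above under all 10 alternatives and Wnt signalling under 6. Epithelial junctions (0.29, percentile 64.5), palate mesenchyme (0.07, percentile 70.0), transformation genes (0.12, percentile 54.2) and interferon response (0.70, percentile 96.5) did not stand apart, although interferon response did under 6 of 10 alternatives. Palate mesenchyme did under 2 of 10, with the mean over probe sets (0.50, percentile 98.9) and with the list mean (0.54, percentile 99.9). Ratios of adjacent genes correlated at r = 0.225, and the Actb 3' to 5' ratio was lower at 24 h than at 12 h.

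The comparison of 24 h with 0 h set transforming seam epithelium against unfused tissue. Interferon response genes again had the highest median, with 23 of 25 members at least 2-fold higher at 24 h and 0 at least 2-fold lower. Gbp3 was at least 79.3-fold higher, Isg15 22.7-fold higher, the immunoproteasome subunit Psmb8 at least 16.4-fold higher and Ifih1 at least 13.1-fold higher. DNA replication genes had 24 of 39 members at least 2-fold lower and 0 at least 2-fold higher. Mcm5 was 8.17-fold, Mcm7 7.13-fold, the ribonucleotide reductase subunit Rrm2 6.61-fold and Mcm4 5.26-fold lower. The other probe set of Mcm5 gave a log2 ratio of -0.60. Mitosis genes had 10 of 35 at least 2-fold lower and 3 at least 2-fold higher, with Cks1b and Kif11 5.17-fold and 4.38-fold lower but Nek2 and Ect2 5.81-fold and 5.37-fold higher. The cell cycle inhibitor Cdkn1a, at 30.8-fold higher, had the highest measured ratio of all genes, and its other probe set gave a log2 ratio of 3.36.

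Matrix proteases and inhibitors had 13 of 25 members at least 2-fold higher at 24 h and 1 at least 2-fold lower. Ctss was 6.61-fold higher, the collagen-degrading cathepsin Ctsk 5.34-fold higher, Ctsl 5.15-fold higher and Mmp9 at least 4.99-fold higher. Genes of glycolysis and hypoxia had 10 of 30 members at least 2-fold higher and 1 at least 2-fold lower. Ddit4 was 17.8-fold higher, Ndrg1, another hypoxia-induced gene, 10.6-fold higher and Pgk1 6.36-fold higher, whereas the hexokinase Hk1 was 7.54-fold lower. Oxidative phosphorylation had 20 of 48 members at least 2-fold lower and 4 at least 2-fold higher, with Atp5l 23.5-fold, Atp5e 18.8-fold, Uqcrh 18.3-fold and Ndufv2 13.1-fold lower, although the other probe set of Ndufv2 gave a log2 ratio of 0.36. Ribosomal protein genes had 7 of 28 at least 2-fold lower, including Rps19 at 7.33-fold and Rps18 at 5.70-fold, and 1 at least 2-fold higher. Cholesterol and fatty acid synthesis genes had 7 of 19 at least 2-fold lower and 1 at least 2-fold higher, with Fasn 4.33-fold and Fdft1 3.66-fold lower.

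**Figure D2:**
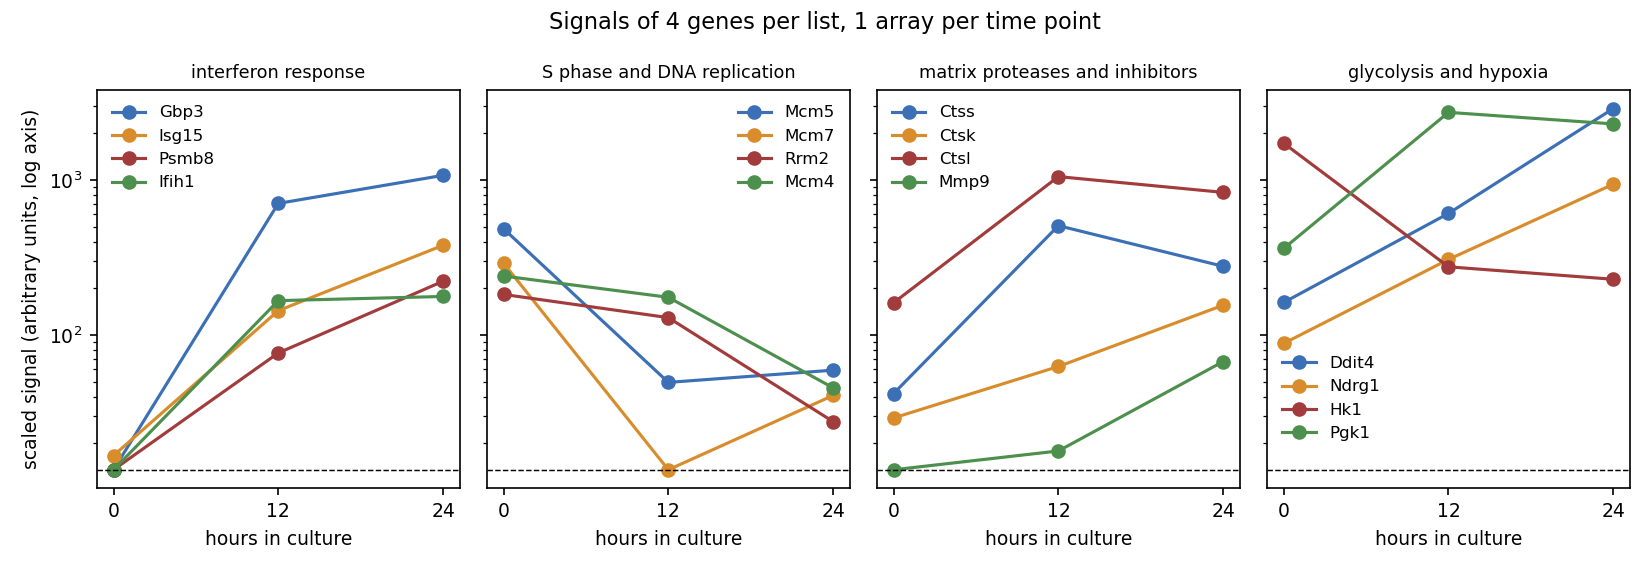
Scaled signals (arbitrary units, log axis) against hours in culture for the 4 members of each of 4 lists with the largest difference between 24 h and 0 h. Each point is 1 array, the dashed line is the floor, and lower signals are drawn at the floor. The interferon response genes are lowest at 0 h, and the replication genes are highest there.

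The 3 epithelial lists stood above random lists at 24 h, that of oral and basal keratinocyte genes under only 4 of 10 alternatives. Junction and polarity genes had 9 of 28 members at least 2-fold higher and 1 at least 2-fold lower, with Pkp1 8.41-fold, Dsc2 7.30-fold, the tight junction scaffold Tjp1 4.37-fold and Krt8 4.34-fold higher. Of 21 periderm and differentiation genes, 6 were at least 2-fold higher and 0 at least 2-fold lower, with the cornified envelope gene Lor 3.85-fold and Krt10 3.82-fold higher. Oral and basal keratinocyte genes had 4 of 20 at least 2-fold higher and 1 at least 2-fold lower. Krt6a, a keratin of activated keratinocytes, was 7.42-fold higher, Krt4, a keratin of the oral lining, 3.28-fold higher, and Sfn, an epithelial 14-3-3 protein, at least 9.71-fold lower. With the values as deposited, the median log2 ratios of the junction, periderm and keratinocyte lists were -0.44, -0.48 and -0.48, against -0.98 over all genes, and lay at percentiles 99.9, 98.7 and 98.6. Cdh1, which encodes E-cadherin, was 1.70-fold lower and Cdh2, which encodes N-cadherin, 3.77-fold lower.

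Palate mesenchyme markers had 12 of 36 members at least 2-fold higher at 24 h and 7 at least 2-fold lower. A different share of carried-over mesenchyme in the 2 samples was not excluded. Col1a2, a chain of type I collagen, was 11.1-fold higher, the matrix glycoprotein Sparc 6.11-fold higher, the collagen crosslinking enzyme Lox 5.36-fold higher and Col5a1 5.12-fold higher. Other probe sets for these genes gave log2 ratios of -0.34 for Col1a2, -0.23 for Lox and -0.25 for Col5a1. Mfap2 and Twist2 were among the 7 lower members, at 4.55-fold and 2.15-fold lower than at 0 h. Transformation genes had 10 of 33 at least 2-fold higher and 5 at least 2-fold lower, among them Mmp13 at least 3.94-fold higher and the repressor Zeb1 3.81-fold higher. The other probe set of Zeb1 gave a log2 ratio of 0.73. Twist1 was 2.77-fold higher, Tgfb3 2.67-fold higher and Smad2 2.24-fold higher. Snai1 was 3.69-fold lower and Snai2 1.56-fold higher. Log2 ratios of Fn1, Lef1, Ctnnb1 and Trp63 were 0.34, 0.05, -0.10 and -0.17. The mesenchymal filament gene Vim had signals of 14.3, 11.9 and 22.4 at 0, 12 and 24 h, close to the floor. The probe sets for Krt5, Krt14, Tgfbr2 and Smad3 were at the floor on all 3 arrays. Tgfbr1 had a signal of 16.8 at 0 h and was at the floor at 12 h and 24 h. TGF-beta and BMP signalling genes had 13 of 39 members at least 2-fold higher and 7 at least 2-fold lower. Klf10, an early TGF-beta target, was 8.35-fold higher, Smad4 4.86-fold higher, Bmp7 at least 5.12-fold lower and Junb 4.63-fold lower.

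Markers of other cell types also differed between 24 h and 0 h. Muscle markers had 5 of 20 at least 2-fold higher, with Tnnt1 4.25-fold higher, and 3 at least 2-fold lower, with Actc1 4.97-fold lower. The other probe set of Tnnt1 gave a log2 ratio of 0.41, and that of Actc1 -2.72. Endothelial markers had 3 of 18 at least 2-fold higher, including Cdh5 at 3.09-fold and Cldn5 at 2.16-fold, and 1 at least 2-fold lower. Neural and glial markers had 5 of 17 at least 2-fold lower and 0 at least 2-fold higher, with the fatty acid binding protein Fabp7 at least 20.2-fold lower, the microtubule protein gene Mapt 4.40-fold and the neuronal gene Dcx 3.41-fold lower, although another probe set of Mapt gave a log2 ratio of 0.64. Leukocyte markers had 5 of 18 at least 2-fold higher and 1 at least 2-fold lower (median log2 ratio 0.14, percentile 83.6). They stood above random lists under 2 of 10 alternatives, at up to percentile 99.2. Besides Cdkn1a, the largest measured ratios were those of Slc31a1 (27.6-fold higher), Isg15, Aldh1a1 (18.3-fold higher, with a log2 ratio of -0.36 from its other probe set) and the lipid transfer gene Osbpl5 (17.9-fold higher), and of Hba-x (40.8-fold lower), Atp5l and the arginine methyltransferase Prmt1 (19.2-fold lower). The other probe set of Slc31a1 gave a log2 ratio of 0.70. Ndrg2, the ATP receptor P2rx4 and the acute phase gene Saa3 were at least 31.1-fold, 23.7-fold and 23.3-fold higher, and Uqcr11 and Dctpp1 at least 27.9-fold and 26.9-fold lower.

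In all, 925 of 6392 genes were at least 2-fold higher at 24 h than at 0 h and 1130 at least 2-fold lower, against at most 889 and 1147 in simulated unchanged genes. After median centring the observed counts were 1049 and 943, and after quantile normalization 1059 and 1001. Second probe sets gave the same direction for 55.6% of 257 genes, repeated the 2-fold difference for 22.2% and were 2-fold different the opposite way for 35 genes. The upward share of 45.0% was 8.36% for values as deposited, 52.7% after median centring and 51.4% after quantile normalization. If genes varied independently, 0.65 of the 26 lists would stand above random lists. Some lists share members, such as Pkp1, and related genes can shift together, so 0.65 cannot serve to measure an excess. In these arrays 9 lists stood above random lists. These were interferon response (median log2 ratio 2.24, percentile 100), matrix proteases (1.01, percentile 100), glycolysis and hypoxia (0.74, percentile 99.6), muscle (0.60, percentile 99.8), periderm (0.51, percentile 98.8), epithelial junctions (0.50, percentile 99.7), endothelial (0.47, percentile 99.6), oral and basal keratinocyte (0.45, percentile 98.1) and TGF-beta and BMP signalling (0.40, percentile 99.4). Another 6 stood below: DNA replication (-1.34, percentile 0), oxidative phosphorylation (-0.72, percentile 0), neural and glial (-0.70, percentile 0.59), cholesterol synthesis (-0.62, percentile 2.04), mitosis (-0.51, percentile 0.55) and ribosomal proteins (-0.22, percentile 0.95). With the values as deposited the medians of the glycolysis, muscle, endothelial and TGF-beta lists were also below 0, as was that over all genes, at -0.42, -0.13, -0.44 and -0.50 and percentiles 98.8, 99.9, 99.0 and 97.3. Under the 60th percentile floor the muscle median was -0.20, at percentile 46.8. The call held under 4 of 10 alternatives for oral and basal keratinocyte genes and under 7 each for the endothelial, TGF-beta and ribosomal protein lists, and under 8 to 10 for the others. Palate mesenchyme (0.27, percentile 73.1) and transformation genes (0.32, percentile 92.8) did not stand apart. The Gapdh 3' to 5' ratio also differed, at 0.828 at 0 h and 12.6 at 24 h. With 1 array per time point, that difference cannot be separated from those of the lists.

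**Figure D3:**
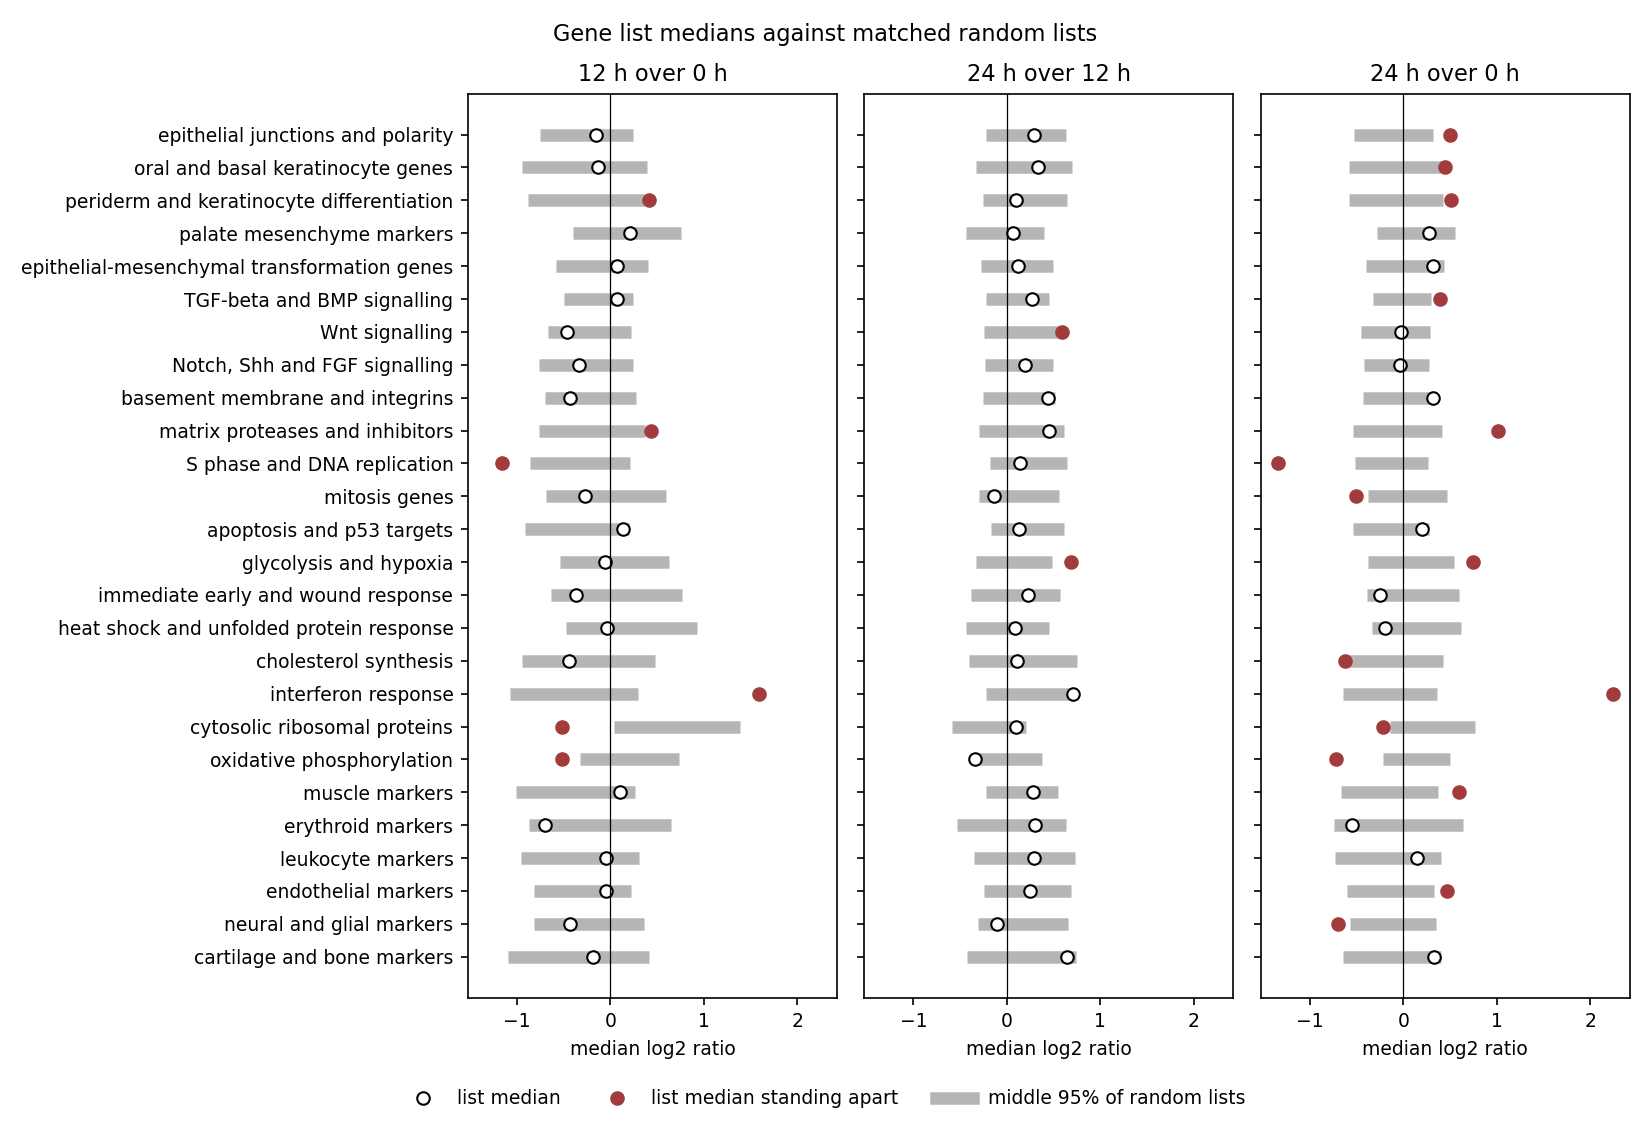
Median log2 ratio of 26 gene lists (points) in the 3 comparisons, with the middle 95% of 10000 random lists matched on signal (grey bars), filled points standing apart from them. Interferon response has the highest median in both comparisons with 0 h, at 1.59 and 2.24, and DNA replication the lowest, at -1.15 and -1.34.

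Comparisons that share the 0 h array share its error. At both 12 h and 24 h, 598 genes were at least 2-fold higher than at 0 h, against 160 for independent lists and up to 557 in simulated unchanged genes. Correspondingly, 803 genes were at least 2-fold lower at both, against 317 and up to 787. The simulated medians were 508 and 719, so most of these overlaps can come from the shared array. Higher signals at each step, by at least 2-fold both times, were found for 37 genes, against up to 17 in the simulation, and Cdkn1a (signals of 15.1, 72.6 and 466) and Ddit4 (162, 609 and 2892) were among them. Lower signals at each step were found for 18 genes, against up to 26.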

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

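Control probe sets, which no comparison uses, carried a signal that set the cultured arrays apart from the 0 h array. The 3' to 5' signal ratio of Gapdh was 14.9 at 12 h and 12.6 at 24 h, above its 0.828 at 0 h. That of Actb was 11.9 at 12 h and 2.97 at 24 h, above its 1.02 at 0 h. The scaled 3' signal of Gapdh was 2897 at 0 h, 668 at 12 h and 3060 at 24 h, and that of Actb 3321, 458 and 990.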

How the results depend on the processing

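The alternative using only the 2 arrays of a comparison was chosen after the data were seen. No paired analysis was possible because each time point has 1 array, and for the same reason no array could be left out within a time point. Signals near the floor limit the values, as the unfloored counts show. The cause of the differences was not tested except where the setting's construction gives it: the 3-fold rule is stricter, a higher floor hides low signals, and values as deposited keep the arrays' unequal means. Genes higher and lower numbered, for 12 h over 0 h, 610 and 972 under the 3-fold rule and 603 and 2984 as deposited, with 1141 lower under the 60th percentile floor. For 24 h over 12 h they numbered 455 and 281 under the 3-fold rule and 1904 and 1257 without a floor, with 660 higher under the 60th percentile floor and 702 higher as deposited. For 24 h over 0 h they numbered 424 and 496 under the 3-fold rule, 296 and 3244 as deposited and 1492 and 1765 without a floor, with 717 lower under the 60th percentile floor. The other 42 counts stayed within 1.5 times. For 24 h over 12 h, palate mesenchyme markers stood above random lists with the mean over probe sets (0.50) and with the list mean (0.54). As deposited, where the median over all genes was -0.98 for 24 h over 0 h, list medians for 24 h over 0 h turned to -0.44 for epithelial junctions, -0.48 for oral and basal keratinocyte genes, -0.48 for periderm, -0.42 for glycolysis, -0.50 for TGF-beta and BMP, -0.44 for endothelial and -0.13 for muscle markers, and that of periderm for 12 h over 0 h to -0.27, yet all stayed above random lists at percentiles of 98.3 or more except TGF-beta and BMP at 97.3. The muscle median was -0.20 under the 60th percentile floor, at percentile 46.8, and no longer stood apart. By percentile alone, 198 of 230 alternative values of lists that stood apart still did and 32 no longer did, and 45 of 550 of the other lists, these 2 included, newly did. Interferon response and DNA replication, in both comparisons with 0 h, stood apart the same way under all 10 alternatives. Interferon response for 24 h over 12 h, not called, stood apart under 6 of 10, while Wnt signalling kept its call for 24 h over 12 h under 6, periderm for 12 h over 0 h under 6 and oral and basal keratinocyte genes for 24 h over 0 h under 4. Of 161 named ratios of at least 2-fold, 1396 of 1436 alternative values kept 2-fold and direction, 37 fell short, and 3 turned: H2-K1 (-0.28) and Itgav (0.17) for 24 h over 12 h without cross-hybridizing suffixes, and Rpl10a (0.91) for 12 h over 0 h after median centring.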

Other observations

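The tests of the interferon and replication patterns were chosen after those results were seen, as were the sex-linked genes, the correlations between neighbouring genes and the repeat of the pair count without neighbours of similar names.

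Immediate early and stress genes went both ways between 24 h and tissue taken without culture. Fosb, an immediate early transcription factor subunit, was 7.20-fold lower at 24 h than at 0 h and the cochaperone Dnajb1 11.1-fold lower, while the mitochondrial chaperone Hspa9 was 12.3-fold and the chemokine Cxcl1 13.1-fold higher. The other probe set of Cxcl1 gave a log2 ratio of 0.96. The immediate early and wound response list had a median log2 ratio of -0.25 (percentile 8.87, with 5 of 28 members at least 2-fold higher and 8 lower), and heat shock and unfolded protein response -0.19 (percentile 8.31, with 5 of 30 higher and 8 lower), so neither stood apart. Under 2 of 10 alternatives the heat shock list stood below random lists. Erythroid markers had 0 of 11 at least 2-fold higher and 4 at least 2-fold lower at 24 h (median -0.55, percentile 11.5). They stood below random lists under 3 of 10 alternatives. Cartilage and bone markers (0.33, percentile 95.4), basement membrane and integrin genes (0.32, percentile 97.2), apoptosis genes and p53 targets (0.20, percentile 94.7), Wnt signalling (-0.03, percentile 64.2) and Notch, Shh and FGF signalling (-0.03, percentile 61.8) did not stand apart at 24 h against 0 h, although cartilage and bone did under 6 of 10 alternatives. The basement membrane and apoptosis lists each stood above random lists under 2 of 10. The X-inactivation transcript Xist had a signal of 226 at 0 h and was at the floor at 12 h and 24 h, and the Y-linked Eif2s3y had signals of 15.6, 147 and 18.8. Of the other Y-linked genes, Kdm5d was at the floor on all 3 arrays and Uty at 0 h and 24 h, with 24.8 at 12 h. The sex of the embryos is not given in the sources used here, and a difference in it between the samples was not excluded.

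Interferon response genes were higher at 24 h than at 0 h, with a median log2 ratio of 2.24. Array scaling is argued against as the whole cause, since the lowest median over 4 scalings was 1.69. More leukocytes in the cultured sample stay open: the upper quartile of leukocyte markers was 0.94, below the lower quartile of the interferon list at 1.70, but the median of the brightest markers at 24 h lay above 1.70 when up to 4 were counted and below it from 5 on, a choice made after their values were seen. The 6 brightest went from 63.0 to 280 (Laptm5), 42.0 to 278 (Ctss), 74.2 to 209 (Cd14), 44.0 to 58.4 (C1qc), 34.7 to 48.3 (Cd68) and 42.9 to 31.9 (Lcp1). The other probe set of Laptm5 gave a log2 ratio of 0.19. Csf1r and C1qb had log2 ratios of -0.30 and -0.22, while 5 of 18 markers were at least 2-fold higher. All probe sets of Ptprc, Lyz2, Adgre1 and Fcer1g were at the floor on all 3 arrays. The leukocyte list stood above random lists under 2 of 10 alternatives. A shift of RNA quality or amplification away from the 0 h array stays open, since between the cultured arrays the list reached percentile 96.5, and stood apart under 6 of 10 alternatives, and a response to culture or fusion may also account for the pattern, untested.

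DNA replication genes were lower at 24 h than at 0 h, with a median log2 ratio of -1.34. Array scaling is argued against as the whole cause, since the highest median over 4 scalings was -1.16. A shift of RNA quality or amplification cannot be told apart from an effect of culture or fusion, because the list lay at percentile 30.7 between the cultured arrays and the unfused tissue was not cultured.

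At 12 h, 764 genes were at least 2-fold lower than at 0 h and at least 2-fold higher again at 24 h, as the Gapdh 3' control was (2897, 668 and 3060), and the Actb 3' to 5' ratio was highest at 12 h (1.02, 11.9 and 2.97). Independent error of the 12 h array is argued against as the whole cause. Simulated unchanged genes gave at most 313 such genes, and independent errors would not gather on chromosomes. That simulated error came from probe sets above the floor on both arrays, so larger error of genes at the floor at 12 h was not covered. Array scaling is argued against as the whole cause, since 609, 559 and 549 such genes were counted as deposited, after median centring and after quantile normalization. The opposite pattern, at least 2-fold higher at 12 h than at 0 h and 24 h, held 419 genes, against up to 403 in the simulation. Among 5945 genes in chromosome order, 147 adjacent pairs were both in the pattern, against a median of 97 and a highest of 123 in 1000 shuffles (146 against 118 without neighbours of similar names). Ratios of adjacent genes correlated across gene pairs at r = 0.208 for 12 h over 0 h and 0.225 for 24 h over 12 h but at 0.0365 for 24 h over 0 h, and for genes 20 apart in order at 0.0806, 0.0871 and 0.00182. A bias of the 12 h array shared by chromosomal regions, as base composition is, is therefore a candidate explanation, but base composition was not measured, genes of a region can also be regulated together, and RNA quality or amplification of the 12 h sample and a response to fusion stay open, untested.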
